A study of Mus musculus with 10 samples.

How the data were processed

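RNA was measured in 10 libraries of primary smooth muscle cells from mouse aorta, 5 from wild type mice (WT) and 5 from mice carrying the Kit alleles W and Wv (WWv). Per the labels' protocols, the cells were freed with collagenase and cultured to passage 2, RNA was isolated with the Omega EZNA kit, and libraries were made with the Nugen Universal Plus mRNA-Seq kit. The deposited values were raw counts per gene, in whole numbers, for 54446 versioned Ensembl mouse gene IDs in every library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, trimmed with Trim Galore 0.4.3 and aligned with STAR 2.5.2a to mm10. The counting step, its strand setting and the annotation release were not given in the sources used here. Genes that overlap another gene, on either strand, and near-identical copies were therefore treated as uncertain. The size of an overlap was not weighed, and it varied widely (17 of 3350 exon bases in Mcam and 852 of 4724 in Htr1b, for example). Sex, age, genetic background, litter and culture batch of the mice were not given in the sources used here.

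Gene symbols, positions and biotypes were taken from GENCODE M21 on GRCm38, the assembly that mm10 names. Without the version suffix 54409 IDs matched, with it 53229 did, and the 37 IDs that did not match held 0.0026% of all counts. A symbol shared by several IDs, as for 101 symbols, was given to the ID with the most counts. Coordinates are 1-based.

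Groups were taken from the labels. The comparison was WWv against WT, fitted with the group as the only term in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method, with TMM normalization and with filterByExpr at a minimum count of 10, which left 15181 genes. A gene was called past the threshold at a Benjamini-Hochberg adjusted p under 0.05 over these genes, and every adjusted p given for a gene comes from this two-sided test unless another tool is named. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the quasi-likelihood F. Counts-per-million values (CPM) were scaled with the TMM factors and are given as mean ± SD of the 5 libraries of a group. The principal components were computed on log2 CPM with a prior count of 2.

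A total of 47 gene lists, of pathways, matrix and signalling groups and of markers of other cell types, were fixed before the data were examined, as were the main test, the rule for named genes and most of the alternatives. A list was tested when at least 5 of its members were tested genes, which held for 43 lists; the lists of lymphocyte, mast cell, erythroid and sex chromosome genes fell short. The list test was camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 43 lists. Beside it stood camera with an estimated correlation and fry, which tests whether a list's own genes move without comparing them with other genes. Members past the threshold were also counted with p adjusted over the list alone.

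The rule named Kit and Kitl always. It then named the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a gene name, a mean of at least 1 CPM, and every WWv library on the same side of every WT library. From each list it named the up to 4 members past the threshold with the largest absolute change or, with none past it, the 1 with the smallest p. This gave 160 different genes, of which the text names some. A further 13 genes were named after their values had been seen: Acta2, Tagln, Cnn1, Gsn, Pecam1, Cdh5, Mki67, Pdgfra, Klf2, Cenpa, Pxn, Cdh11 and Cd248.

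The procedure was tested on simulated data made from the means and library sizes of the real libraries. Changed genes were drawn from those above a mean of 1 CPM in WT, and counts were drawn independently for each gene. Of the simulated changes in the WWv against WT comparison over 15021 genes, 71.6% of those of 1.5-fold, 89.6% of those of 2-fold and 98.5% of those of 4-fold were recovered, and 12 of 201 calls (5.97%) were false. Totals ranged from 42040255 to 53863661 counts per library, and the common biological coefficient of variation was 0.161. Shares of counts in a single library carry 95% Wilson intervals, which cover counting error only, since reads are not independent molecules.

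The alternatives changed 1 choice at a time: RLE, upper quartile or library size only in place of TMM, no low-count filter or 1 CPM in 5 libraries, robust dispersions, other thresholds, a minimum fold change, mitochondrial genes left out, limma-voom with and without sample quality weights, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a fit without WT 2 and WWv 1 and a fit with the mean log2 CPM of the cell cycle list as a covariate (the cell cycle score). The correction for gene length and GC content removed from each library the smooth trend of its log2 CPM with exon length and GC content. That trend included a constant for each library, so the correction also shifted log2 fold changes of all genes in common. The mean log2 CPM of a list was also fitted on group with the mean of the fibroblast or cell cycle list as a covariate. Differences in library measures were tested by exact permutation over all 252 assignments of the 10 libraries. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures, and random draws used the seed 1. No library and no column of values was left out. Reads were not realigned, and transcript isoforms and sequence variants were not analysed here. Results for some genes are not reported here.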

Results

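Messenger RNA was sequenced from primary aortic smooth muscle cells of wild type mice (WT) and of mice with the Kit alleles W and Wv (WWv), with 5 libraries per group. The sample titles number the libraries and do not say whether each came from a separate mouse. Kit encodes c-Kit, the receptor tyrosine kinase for stem cell factor. The W allele carries a splice mutation that removes the transmembrane part of the receptor, and the Wv allele carries a missense change in the kinase domain, so neither allele need lower the transcript. Gene counts totalled 47221911, 43634774, 49651053, 51309067 and 42040255 in WT replicates 1 to 5. In WWv replicates 1 to 5 they totalled 45225270, 44929825, 43455518, 47221935 and 53863661. Depth did not separate the groups (46771400 ± 3914970 in WT and 46939200 ± 4096930 in WWv, SD, n = 5 each, two-sided exact permutation p = 0.944, adjusted p = 0.944 over 5 library measures). The 10 most abundant genes took 10.6 ± 0.699% of the counts in WT and 11.9 ± 0.509% in WWv (n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0198, higher in 5 of 5 WWv libraries than in any WT library). Mitochondrial transcripts took 1.94 ± 0.305% and 1.98 ± 0.284% (exact permutation p = 0.833, adjusted p = 0.944). The TMM normalization factor was 1.03 ± 0.0206 in WT and 0.971 ± 0.0131 in WWv (n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0198). The scaling itself thus differed between the groups, with every WWv library below every WT library.

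On the first principal component, with 52.5% of the variance, 4 of the 5 WT libraries lay between −51.1 and −29.1 and the 5 WWv libraries between 11.5 and 33.4. WT 2 lay at 20.2, within the WWv range, and stood apart from all other libraries on the second component at −42.9 (17.3% of the variance). Its Kit level, 4.92 CPM, was the highest of the 10 libraries.

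**Figure D1:**
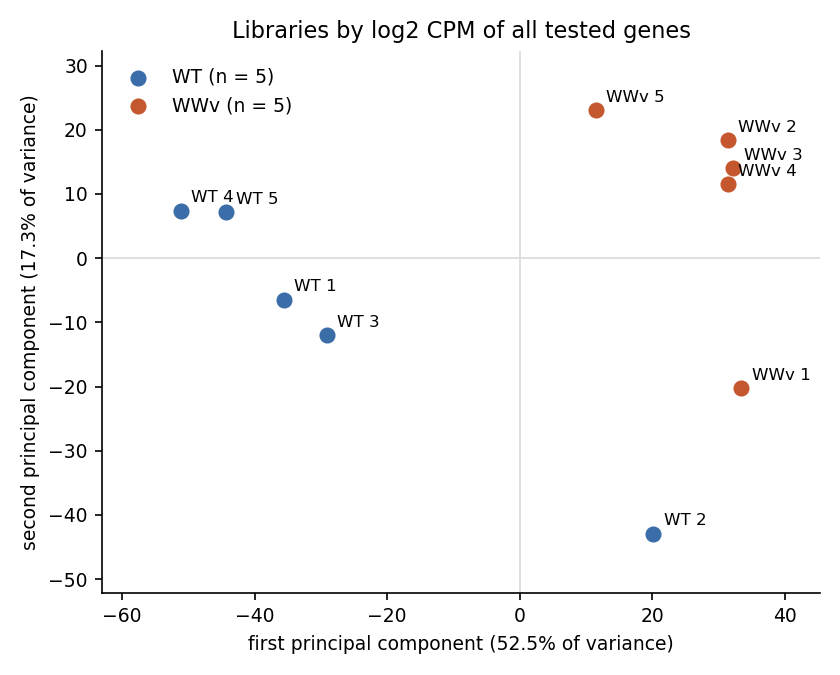
Positions of the 10 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, in arbitrary units, with each point a library coloured by group (n = 5 WT and 5 WWv). WT 2 lies at 20.2 on the first component, inside the WWv range of 11.5 to 33.4.

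The comparison of WWv with WT cells addressed which transcripts differ when vascular smooth muscle is without normal c-Kit signalling. Kit fell by 1.04 on the log2 scale, from 4.12 ± 0.629 CPM in WT to 2.00 ± 0.764 CPM in WWv (n = 5 each), and the transcript of its ligand Kitl fell too. Of 24 genes of the contractile apparatus 17 rose, among them Acta2, the smooth muscle actin, by 1.68-fold and Myh11, the smooth muscle myosin heavy chain, by 2.05-fold. Lower were 9 of 14 complement genes, 19 of 30 genes of glycolysis and the response to hypoxia, and 10 of 25 genes of cholesterol synthesis, with Bnip3, a hypoxia-induced mitophagy receptor, 2.61-fold lower. Cell cycle genes were higher in 15 of 39 members and lower in 1. The contractile, complement, glycolysis and hypoxia, cholesterol and cell cycle lists passed camera at its preset correlation between genes and did not pass at an estimated one. WT 2 lay with WWv in the complement list (mean 2.94 log2 CPM, WWv 2.87 to 3.37) and above WWv in the cell cycle list (5.76, WWv 5.48 to 5.69). With the cell cycle score as a covariate the complement median shrank to 0.206 of its size. The nuclear RNA Neat1, the scaffold of paraspeckles, was 4.28-fold lower.

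Kit (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722, plus strand, mm10) stood at 3.19, 4.92, 4.07, 4.40 and 4.02 CPM in WT replicates 1 to 5. In WWv replicates 1 to 5 it stood at 2.09, 0.929, 1.71, 3.01 and 2.25 CPM. Every WWv library lay below every WT library, a 2.06-fold difference (log2 fold change −1.04 ± 0.25 SE, edgeR adjusted p = 0.0122). Against a minimum log2 fold change of 1 the difference did not pass (adjusted p = 1). Kitl, which encodes stem cell factor (ENSMUSG00000019966.18, chromosome 10, 100015630 to 100100416), fell from 67.7 ± 16.4 to 29.9 ± 6.16 CPM (log2 fold change −1.18 ± 0.18, adjusted p = 0.00153). Stat5a, a transcription factor activated by cytokine receptors and by c-Kit, fell by 0.54 ± 0.08 (adjusted p = 0.0017), although Stat3 overlaps it on the opposite strand and its reads are uncertain. Among all 29 tested components of Kit signalling 7 rose and 9 fell (7 and 10 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.925). Its median change was 0.02, its mean −0.11 and its test direction down, and the median turned to −0.06 with library size only. Without WWv 4 the members that rose numbered 4.

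**Figure D2:**
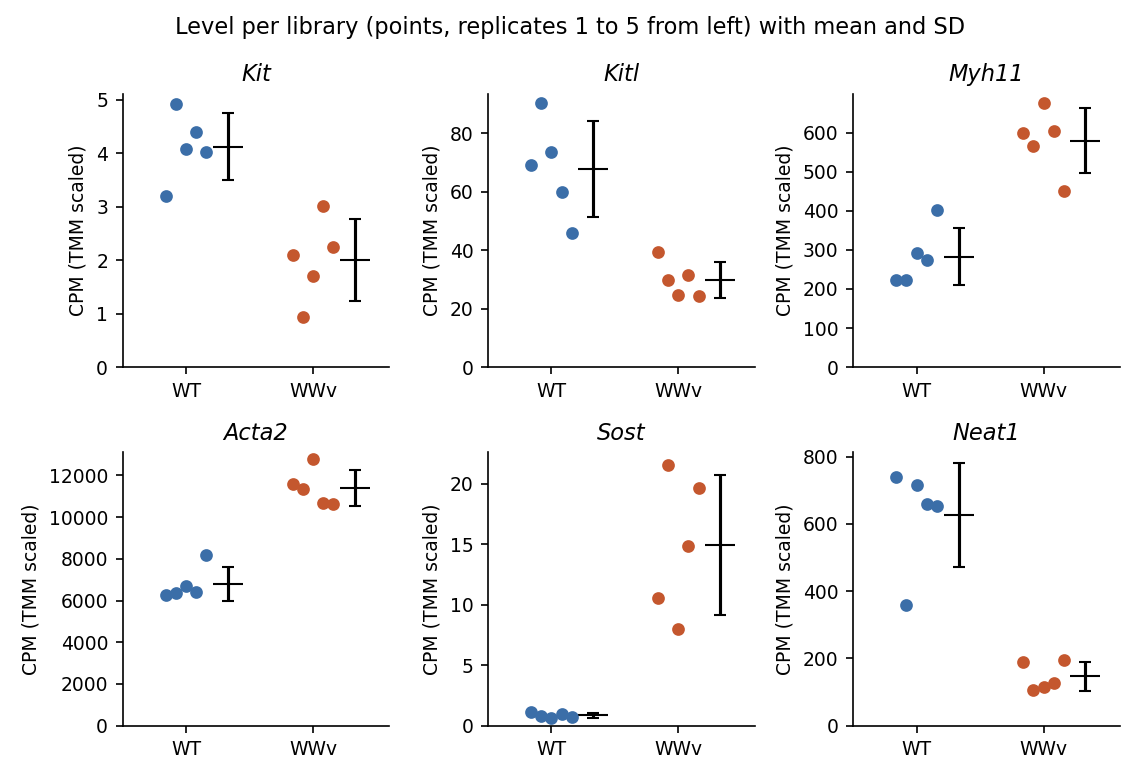
Level of Kit, Kitl, Myh11, Acta2, Sost and Neat1 (vertical axes, CPM from 0) in each library, with points for WT and WWv replicates 1 to 5 from left to right and the mean with SD beside them (n = 5 each). In all 6 genes every WWv library lies on one side of every WT library.

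Past the threshold were 4274 of 15181 tested genes (28.2%), 1940 higher and 2334 lower in WWv, with 6236 genes at an unadjusted p under 0.05. The median absolute log2 fold change of the called genes was 0.42, and 749 changed at least 2-fold, 137 upward and 612 downward. Called protein coding genes split nearly evenly (1882 higher, 1970 lower of 13195 tested), whereas called long noncoding RNA genes were mostly lower (38 higher, 233 lower of 1074 tested). Noncoding RNA genes took 0.764 ± 0.0521% of the counts in WT and 0.611 ± 0.110% in WWv (n = 5 each, exact permutation p = 0.0476, adjusted p = 0.0794, lower than every WT library in 4 of 5 WWv libraries), a difference that failed the correction. WWv 1 held 0.802% (95% Wilson interval 0.799 to 0.804%), and WT 2 held 0.676% (0.674 to 0.678%). In 2409 genes (15.9%, against 0.794% by chance) all WWv libraries lay on one side of all WT libraries, 2281 of them past the threshold. With library size only in place of TMM the calls split into 983 higher and 3599 lower, so that 21.5% rather than 45.4% were higher, and the median change of all genes moved from −0.01 to −0.09.

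Single libraries moved these counts. Without WT 2 there were 7127 calls (3507 higher, 3620 lower), which held 4249 of the 4274 genes with the same sign, and 285 and 936 genes changed at least 2-fold upward and downward. Without WWv 2 or WWv 4 the higher calls numbered 1292 and 1286. Higher long noncoding calls numbered 65 without WT 2, 25 without WT 3 or WT 4, 24 without WWv 3 and 22 without WWv 4. Of the genes named here as past the threshold, Itgb8, Serping1, C3, Pdk1, Lum, Col6a1, Vegfd, Sfrp1, Pdgfra, Ddx3y, Cenpa, Pxn, Cdh11, H2-T23, Dpep1, Abcc9, Kcnj8, Gas5, Dusp4, Spry4, Alpl, Upk1b, Mitf, Tnnt3, Hoxa11, Lck, Dnaja1 and Dll1 overlapped between the groups, with 5 of 5 WWv libraries on the called side of the WT mean. In all others the 5 WWv libraries lay on one side of the 5 WT libraries.

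The largest rise among genes with no overlap between the groups was that of Sost (ENSMUSG00000001494.6, chromosome 11, 101962458 to 101967015), which encodes the secreted Wnt antagonist sclerostin. It went from 0.846 ± 0.202 to 15.0 ± 5.79 CPM (17.6-fold, log2 fold change 4.14 ± 0.30, adjusted p = 7.76e-05). Ptprz1, a receptor tyrosine phosphatase best known from glia (chromosome 6, 22875502 to 23052916), rose from 4.51 ± 2.42 to 36.9 ± 6.64 CPM (8.21-fold, adjusted p = 0.000304). Mcam, the adhesion molecule CD146 of vascular wall cells (chromosome 9, 44134469 to 44142727), rose 3.89-fold from 63.9 ± 11.4 to 248 ± 36.4 CPM (adjusted p = 6.67e-05). The other large rises were those of Kank4 (log2 fold change 2.87), Smpd3, a neutral sphingomyelinase (2.24), the connexin gene Gja3 (2.08), Ifi27l2b (1.88), the transcription factor gene Creb5 (1.82), the serotonin receptor gene Htr1b (1.76) and Olfm2 (1.76).

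Saa3, an acute phase serum amyloid gene (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700), fell from 4.40 ± 3.06 to 0.132 ± 0.0327 CPM (32.8-fold lower, log2 fold change −5.03 ± 0.68, adjusted p = 0.000875). Steap4, an inflammation-regulated metalloreductase (chromosome 5, 7960457 to 7982213), was 30.7-fold lower (4.10 ± 2.05 and 0.130 ± 0.0749 CPM, adjusted p = 0.000454). Cxcl5, a chemokine that attracts neutrophils (chromosome 5, 90759360 to 90761624), was 10.9-fold lower (5.51 ± 0.998 and 0.507 ± 0.201 CPM, adjusted p = 8.77e-05). Also among the largest falls were those of Stc1, the calcium-regulating hormone stanniocalcin (log2 fold change −4.51), Gdpd2 (−4.28), the aggrecan-cleaving protease gene Adamts15 (−4.15), Lgi2 (−4.10), Fmo1 (−4.05), the growth factor gene Gdf10 (−3.94) and Hp, the haemoglobin-binding haptoglobin (−3.69). WT 2 was the lowest of the WT libraries for each of the 10 falls except Cxcl5 (Stc1 at 4.42 against 19.2 to 60.2 CPM, for example) and the highest for Ptprz1, Smpd3, Gja3, Ifi27l2b, Creb5, Htr1b and Olfm2 among the 10 rises. With the cell cycle score as a covariate the call of Adamts15 was lost (log2 fold change −2.75, adjusted p = 0.0574), and the changes of Gja3 (1.29), Saa3 (−3.07), Stc1 (−2.48), Gdpd2 (−1.77), Lgi2 (−2.27), Gdf10 (−2.14) and Hp (−1.78) shrank by more than 1.5 times with their calls kept. Smpd3, Mcam, Htr1b, Stc1 and Gdpd2 overlap genes on the opposite strand and Creb5 overlaps a small RNA gene on its own strand, so their reads are uncertain.

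**Figure D3:**
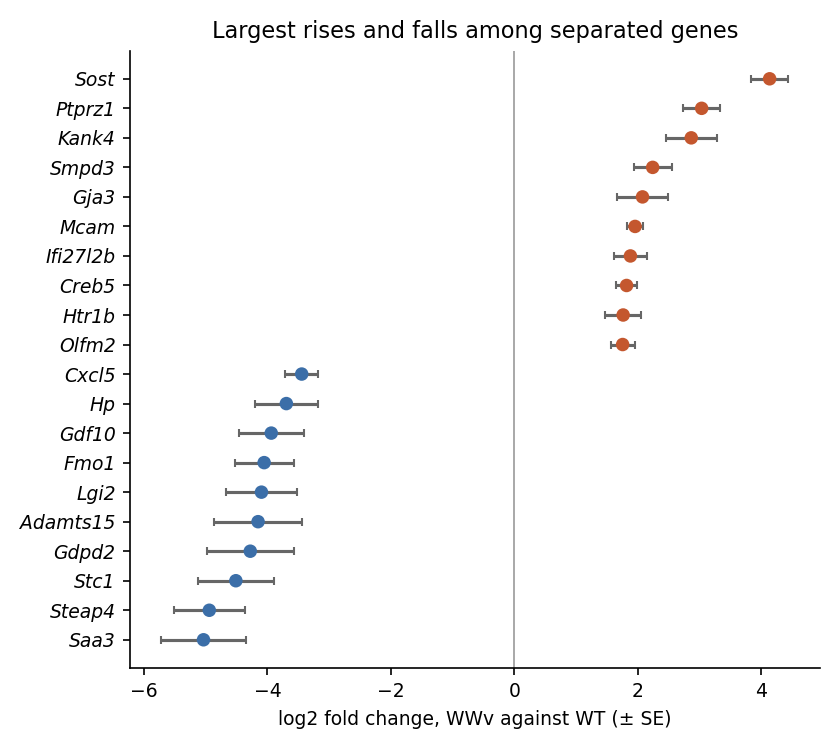
Log2 fold change of WWv against WT (horizontal axis, points with SE) for the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (n = 5 each). Values run from −5.03 for Saa3 to 4.14 for Sost.

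The contractile apparatus had the smallest camera p of the 43 lists tested, with 17 of its 24 tested members higher and 0 lower (19 and 0 adjusted over the list alone; median log2 fold change 0.44; camera adjusted p = 7.08e-10). With an estimated correlation between genes the list did not pass (adjusted p = 0.73 with an estimated correlation). Acta2 (chromosome 19, 34241090 to 34255590) rose from 6777 ± 815 to 11395 ± 879 CPM (log2 fold change 0.75 ± 0.10, adjusted p = 0.000676), with WT 5 at 8205 CPM, the highest of WT. Myh11 (chromosome 16, 14194535 to 14291372) rose from 283 ± 73.2 to 579 ± 82.7 CPM (1.03 ± 0.16, adjusted p = 0.00178). Synpo2, an actin-bundling Z-disc protein, rose by 1.10 ± 0.15 (adjusted p = 0.001), Tagln, the calponin-related SM22, by 0.73 ± 0.08 (adjusted p = 0.000461) and Cnn1, calponin, by 0.70 ± 0.13 (adjusted p = 0.00324). Acta2, Tagln and Cnn1 were chosen after their values were seen. Myocd, which encodes the SRF coactivator myocardin that drives contractile genes, rose by 1.13 ± 0.19 (adjusted p = 0.00201). Of the 21 myocardin and SRF regulators 6 rose, Mef2a among them by 0.34 ± 0.07 (adjusted p = 0.00485), and 0 fell (6 and 0 adjusted over the list alone). That list did not pass (camera adjusted p = 0.361), and its median of 0.02 turned to −0.06 with library size only. Without WT 2 there were 4 lower regulators, and without WWv 1 or WWv 5 there were 2. The call of Mef2a was lost with the cell cycle score as a covariate (0.22, adjusted p = 0.0784). WT 2 did not lie with WWv in the contractile list, where its mean level of 8.16 log2 CPM was below the 8.71 to 9.00 of WWv.

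Immediate early genes, which respond to growth factors and stress within minutes, rose in 5 of 16 members and fell in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00432; adjusted p = 0.741 with an estimated correlation). The 5 were Fosb (log2 fold change 1.01), Egr2 (0.91), Egr1 (0.87 ± 0.14, adjusted p = 0.00165), Ier2 (0.85) and Klf2 (0.59, chosen after its values were seen). The list was not past the threshold when WT 2 and WWv 1 were both left out (camera adjusted p = 0.0666). Fosb lost its call without WT 4 (0.94, adjusted p = 0.0578) and without WT 5 (0.92, adjusted p = 0.0563), its change shrank to 0.64 without WWv 1, and its call was lost with the cell cycle score as a covariate (1.03, adjusted p = 0.109). The TGF-beta response, which supports the contractile state and matrix production, rose in 12 of 25 members and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.00537; adjusted p = 0.73 with an estimated correlation). Its ligand gene Tgfb3 rose by 0.82 ± 0.15 (adjusted p = 0.0037), the cell cycle inhibitor gene Cdkn2b by 0.65 and the feedback inhibitor gene Pmepa1 by 0.53, while Tgfbr3, the coreceptor betaglycan, was the 1 that fell (−1.30 ± 0.15, adjusted p = 0.000468). Without WT 2 there were 3 lower members. Integrins and focal adhesion genes rose in 14 of 34 members and fell in 3 (14 and 5 adjusted over the list alone; camera adjusted p = 0.00123; adjusted p = 0.296 with an estimated correlation).

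Among the adhesion genes that rose were the caveolin genes Cav2 (log2 fold change 0.69) and Cav1 (0.68). The 3 that fell were Itgb8, an integrin that activates latent TGF-beta (−1.86 ± 0.44, adjusted p = 0.0115), Cdh11, a mesenchymal cadherin (−0.21), and Pxn, the adaptor paxillin (−0.18), the last pair chosen after their values were seen. Leaving out WT 1, WT 3, WT 4, WWv 2, WWv 3 or WWv 4 left 1 lower member, and leaving out WT 2 gave 6. Pxn was not called without WT 1 (−0.16), WT 3 (−0.18), WT 4 (−0.18), WWv 2 (−0.19), WWv 3 (−0.16) or WWv 4 (−0.19). Cdh11 was not called without WT 1 (−0.19), WT 3 (−0.18), WT 4 (−0.20), WT 5 (−0.22), WWv 1 (−0.18), WWv 2 (−0.22), WWv 3 (−0.21) or WWv 4 (−0.19). Neither passed without the low-count filter. With the cell cycle score as a covariate the calls of Cav1 (0.36, adjusted p = 0.0991), Itgb8 (−0.61, adjusted p = 0.502) and Cdh11 (−0.13, adjusted p = 0.407) were lost, that of Cav2 was kept at 0.37, and Cdkn2b rose by 1.04. Tagln, Mef2a and Tgfb3 overlap genes on the opposite strand and Tgfbr3 one on its own, so their reads are uncertain.

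**Figure D4:**
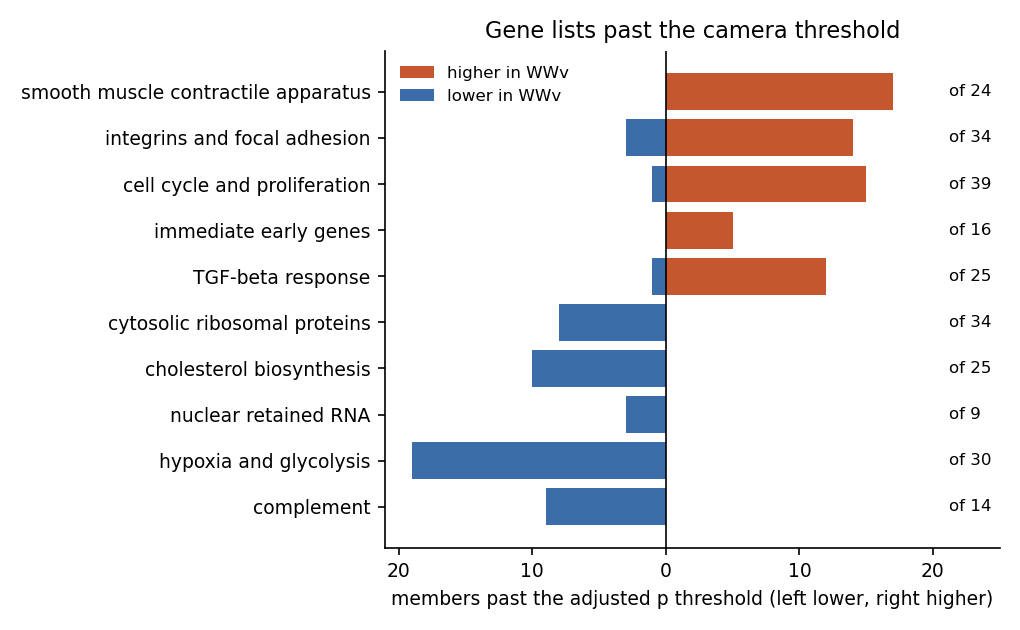
Number of members past the threshold (horizontal axis, lower in WWv to the left and higher to the right) for the 10 lists past the camera threshold, with the number of tested members at the right. The contractile list has 17 of 24 members higher and the hypoxia and glycolysis list 19 of 30 lower.

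Cell cycle genes were higher in 15 of 39 members and lower in 1 (20 and 1 adjusted over the list alone; median log2 fold change 0.29; camera adjusted p = 2.58e-07; adjusted p = 0.741 with an estimated correlation). Among the higher members were Ccne2 (0.93 ± 0.09, adjusted p = 0.000247) and Ccne1 (0.85 ± 0.10, adjusted p = 0.000446), the cyclins E, and Cdc6, which loads the replicative helicase (0.79 ± 0.13, adjusted p = 0.00176). Mki67, a marker of cycling cells chosen after its values were seen, did not pass (0.25 ± 0.14, adjusted p = 0.198). The 1 lower member was Cenpa, the centromeric histone, also chosen after its values were seen (−0.33 ± 0.10, adjusted p = 0.0273). The call of Cenpa was lost without WT 1 (−0.33), WWv 1 (−0.31), WWv 2 (−0.32), WWv 3 (−0.29) or WWv 4 (−0.31). The mean level of the list was highest of all libraries in WT 2, at 5.76 log2 CPM against 5.06 to 5.22 in the other WT libraries and 5.48 to 5.69 in WWv. Without WT 2 the higher members numbered 36 and Mki67 passed (0.42, adjusted p = 0.000781). Higher members numbered 7 without WT 1, WWv 2 or WWv 4, 8 without WT 3, WT 4, WWv 3 or WWv 5, and 9 without WT 5. With library size only 8 rose and 1 fell. The fit with the cell cycle score, which comes from this list, gave 0.49 for Cdc6, −0.50 for Cenpa and −0.11 for Mki67. Ccne2 overlaps Ints8 on the opposite strand, so its reads are uncertain.

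Targets and feedback regulators of the MAPK pathway rose in 2 of 14 members, the phosphatase gene Dusp4 (log2 fold change 0.68) and the feedback inhibitor gene Spry4 (0.33), and fell in 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.114). Without WT 2, whose mean level of this list lay above both groups, 8 members rose and the list passed (camera adjusted p = 0.0162). The p53 and senescence list rose in 8 of 22 members and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0859), with Pmaip1, the proapoptotic NOXA, higher by 0.64 ± 0.11 (adjusted p = 0.00213). The lower members numbered 4 without WT 2 and 1 without WWv 3, where the list passed (camera adjusted p = 0.0481). With the cell cycle score as a covariate the MAPK list changed direction, the calls of Dusp4 (0.49, adjusted p = 0.13) and Spry4 (0.40, adjusted p = 0.0613) were lost, and Pmaip1 kept its call at 0.41.

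Complement genes fell in 9 of 14 members and rose in 0 (11 and 0 adjusted over the list alone; median log2 fold change −0.98; camera adjusted p = 0.00537; adjusted p = 0.741 with an estimated correlation). Serping1, the C1 inhibitor, fell from 263 ± 115 to 121 ± 23.7 CPM (−1.12 ± 0.31, adjusted p = 0.0222), and C3, the central component, from 56.3 ± 29.4 to 19.3 ± 5.86 CPM (−1.54 ± 0.47, adjusted p = 0.032). WT 2 lay with WWv in this list, at a mean level of 2.94 log2 CPM against 3.83 to 4.30 in the other WT libraries and 2.87 to 3.37 in WWv, and held 7.96 CPM of C3. Without WT 2 the list had 13 lower members and 1 higher. Lower members numbered 5 without WT 1, WT 4, WT 5 or WWv 2. Serping1 lost its call without WT 4 (−0.94, adjusted p = 0.0552), WT 5 (−0.99, adjusted p = 0.053) or WWv 2 (−1.06, adjusted p = 0.0551). C3 lost it without WT 1 (−1.47), WT 3 (−1.58), WT 4 (−1.43), WT 5 (−1.37), WWv 1 (−1.46), WWv 2 (−1.57), WWv 3 (−1.45) or WWv 4 (−1.52), and in limma-voom (−1.23, adjusted p = 0.152). With the cell cycle score as a covariate the list had a median of −0.20 and did not pass (camera adjusted p = 0.0574), Serping1 stood at −0.05 (adjusted p = 0.924) and C3 at 0.30 (adjusted p = 0.728).

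NF-kB target genes fell in 7 of 27 members and rose in 0 (7 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.077), although it did without WT 4 (0.0258), WWv 1 (0.0435) or WWv 3 (0.0462) and with the cell cycle score as a covariate (0.00253). The members that fell included Bcl3, an atypical inhibitor of NF-kB (−1.72 ± 0.19, adjusted p = 0.000402), the chemokine gene Cxcl1 (−1.02 ± 0.21, adjusted p = 0.00611) and the adhesion receptor gene Icam1 (−0.88 ± 0.12, adjusted p = 0.000788). Without WT 2 there was 1 higher member. Interferon response genes fell in 7 of 36 members and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.0567), with Gbp2, an interferon-induced GTPase, at −0.84 ± 0.13 (adjusted p = 0.00142). The interferon list passed without WT 1 (camera adjusted p = 0.022), WT 2 (0.0273), WT 3 (0.00924), WWv 4 (0.0244) or WWv 5 (0.0145), and after correction for gene length and GC content (0.0123). Lower interferon genes numbered 12 without WT 2, which also gave 1 higher, 4 without WT 1 or WWv 4, 3 without WT 4 or WWv 3, and 2 without WT 5 or WWv 2. Antigen presentation genes fell in 3 of 15 members and rose in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.077): Psmb8, an immunoproteasome subunit (−1.22 ± 0.16, adjusted p = 0.000875), and the class I genes H2-T23 (−0.74 ± 0.18, adjusted p = 0.0109) and H2-K1 (−0.31 ± 0.09, adjusted p = 0.0205). The antigen presentation list passed without WT 1 (camera adjusted p = 0.0304) or WT 3 (0.0482). H2-K1 lost its call without WWv 2 (−0.30, adjusted p = 0.0533), lower members numbered 6 without WT 2 and 5 without WWv 5, and 1 rose without WT 5. With the cell cycle score as a covariate H2-T23 (−0.20, adjusted p = 0.326) and H2-K1 (−0.30, adjusted p = 0.119) lost their calls, and Gbp2 kept its call at −0.53. Class I genes are near-identical copies, and Bcl3, Icam1, Gbp2 and Psmb8 overlap genes on the opposite strand, so their reads are uncertain.

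**Figure D5:**
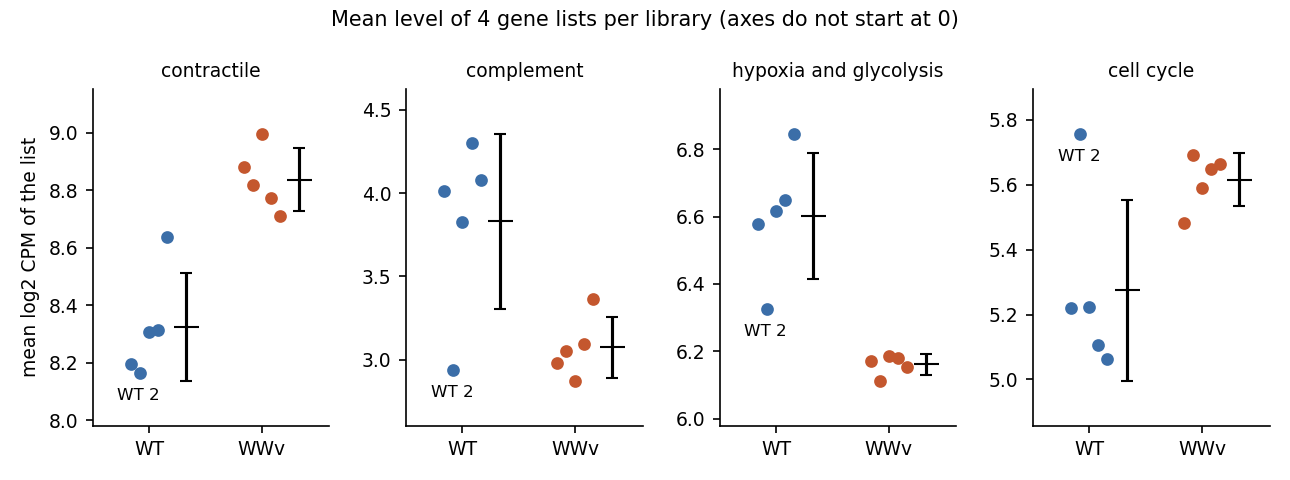
Mean log2 CPM (vertical axes, not starting at 0) of the contractile, complement, hypoxia and glycolysis, and cell cycle lists in each library, with points for replicates 1 to 5 from left to right and the mean with SD beside them (n = 5 each). WT 2 lies at 2.94 in the complement list, within WWv, and at 8.16 in the contractile list, below every WWv library.

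Genes of glycolysis and the response to hypoxia fell in 19 of 30 members and rose in 0 (20 and 0 adjusted over the list alone; median log2 fold change −0.39; camera adjusted p = 5.66e-08; adjusted p = 0.73 with an estimated correlation). Bnip3 (chromosome 7, 138890836 to 138909519) fell by 1.39 ± 0.18 (adjusted p = 0.000712), Pdk1, the kinase that restrains pyruvate oxidation, by 1.11 ± 0.22 (adjusted p = 0.00499) and Adm, the vasodilator peptide adrenomedullin, by 0.91 ± 0.17 (adjusted p = 0.00414). The mean level of the list was 6.11 to 6.19 log2 CPM in WWv, 6.32 in WT 2 and 6.58 to 6.85 in the other WT libraries. Pdk1 lost its call with the cell cycle score as a covariate (−0.42, adjusted p = 0.124), and Bnip3 kept its call at −0.86. Genes of cholesterol synthesis fell in 10 of 25 members and rose in 0 (12 and 0 adjusted over the list alone; median −0.27; camera adjusted p = 0.000135; adjusted p = 0.741 with an estimated correlation). Fdft1, squalene synthase (−0.54 ± 0.09, adjusted p = 0.00233), and Srebf2, the master regulator of the pathway (−0.47 ± 0.08, adjusted p = 0.00271), were among them, and without WT 2 there were 17 lower members. The cholesterol list did not pass with the cell cycle score as a covariate (camera adjusted p = 0.116), where Fdft1 stood at −0.35. Bnip3 and Fdft1 overlap genes on the opposite strand, so their reads are uncertain.

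Cytosolic ribosomal protein genes fell in 8 of 34 members and rose in 0 (8 and 0 adjusted over the list alone; median −0.12; camera adjusted p = 0.000145; adjusted p = 0.741 with an estimated correlation), with Rpl10a at −0.30 ± 0.05 (adjusted p = 0.00289) and Rps4x at −0.26 ± 0.06 (adjusted p = 0.0088). Lower members numbered 13 without WWv 1, 5 without WT 1 or WT 5, and 4 without WT 3, WWv 2, WWv 3, WWv 4 or WWv 5; with library size only there were 16. After correction for gene length and GC content the list did not pass (camera adjusted p = 0.114), and its median went from −0.12 to −0.0085. Much of that move was shared by other genes. The correction changed log2 fold changes by a median of 0.085 in absolute size (SD of the change 0.039 over genes), and the oxidative phosphorylation median rose from 0.04 to 0.15. Ribosomal protein genes have many processed copies in the genome, and their reads are uncertain. The list named for nuclear retained RNAs, which also holds small nucleolar RNA hosts, fell in 3 of 9 members and rose in 0 (3 and 0 adjusted over the list alone, median −0.36, camera adjusted p = 0.0373, adjusted p = 0.741 with an estimated correlation). Neat1 (chromosome 19, 5824708 to 5845478) fell from 626 ± 154 to 146 ± 42.2 CPM (−2.10 ± 0.23, adjusted p = 0.000388), and the small nucleolar RNA hosts Snhg12 (−0.51 ± 0.08, adjusted p = 0.00192) and Gas5 (−0.36 ± 0.08, adjusted p = 0.0107) fell less. In WT 2 Neat1 stood at 359 CPM, below the 654 to 740 CPM of the other WT libraries. This list's call was lost with library size only (camera adjusted p = 0.0657), without WT 5 (0.074), without WWv 2 (0.0764), without WWv 3 (0.051) and with the cell cycle score as a covariate (median 0.03, adjusted p = 0.731), and without WT 2 it had 6 lower members. Gas5 lost its call with the cell cycle score as a covariate (−0.17, adjusted p = 0.185), and Snhg12 kept its call at −0.30. Neat1, Snhg12 and Gas5 contain small RNA genes on their own strand, so their reads are uncertain.

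With all libraries no list of markers of another cell type passed camera, although the macrophage list did in most fits without 1 library, and the endothelial list did, downward, with the cell cycle score as a covariate (camera adjusted p = 0.02). Endothelial genes rose in 2 of 18 tested members and fell in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.714): the phosphatase gene Ptprb (1.43 ± 0.31, adjusted p = 0.00813) and the TGF-beta coreceptor gene Eng (0.22 ± 0.05, adjusted p = 0.0109) rose and the transcription factor gene Erg fell (−1.45 ± 0.30, adjusted p = 0.00627). Of the 19 genes listed, 18 passed the count filter in these smooth muscle cultures and 4 belong to another list. The median of the list was 0.10, its mean −0.01 and its test direction up. The junction genes Pecam1 and Cdh5, chosen after their values were seen, were highest in WT 2, at 90.6 and 107 CPM, against 14.9 to 23.3 and 19.8 to 30.9 CPM in the other WT libraries. In WWv they stood at 23.4 to 57.7 and 29.9 to 76.3 CPM. Neither passed with all libraries (0.19 ± 0.48, adjusted p = 0.787, and 0.37 ± 0.47, adjusted p = 0.583, above the WT mean in 3 of 5 WWv libraries each). Both passed without WT 2 (0.98, adjusted p = 0.00604, and 1.11, adjusted p = 0.0043), where 9 members of the list rose and 1 fell; without WT 4 there were 2 lower members, and Pecam1 stood at −0.01 without WWv 4. Eng, which overlaps Fpgs, was not called with library size only (0.14, adjusted p = 0.0938), and Eng (0.17, adjusted p = 0.124) and Erg (−0.87, adjusted p = 0.107) lost their calls with the cell cycle score as a covariate, where Ptprb stood at 0.78, Pecam1 at −0.50 and Cdh5 at −0.27.

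Adventitial fibroblast genes fell in 5 of 19 members and rose in 1 (5 and 1 adjusted over the list alone; median −0.52; camera adjusted p = 0.232). Lum, the collagen-binding lumican (−4.02 ± 0.66, adjusted p = 0.00209), Dpt, dermatopontin (fell by 2.00 ± 0.27, adjusted p = 0.000858), Cygb, cytoglobin (−1.70 ± 0.27, adjusted p = 0.0017), Dpep1 (−1.52 ± 0.31, adjusted p = 0.00581) and Pdgfra (−0.64 ± 0.13, adjusted p = 0.00631) fell. Gsn, the actin-severing gelsolin, rose (0.52 ± 0.07, adjusted p = 0.000676). Pdgfra and Gsn were chosen after their values were seen. WT 2 held 2.63 CPM of Lum against 23.2 to 49.7 CPM in the other WT libraries and 1.10 to 3.23 CPM in WWv, and without it 8 members fell and 3 rose. Over the members tested without WT 2, the mean level of the fibroblast list lay 0.77 below the other WT libraries in WT 2 and 0.78 below them in WWv, beside 1.08 and 1.09 for the complement list. Lum did not pass in limma-voom (−3.60, adjusted p = 0.0554), and Lum (−1.52, adjusted p = 0.0709), Dpep1 (−0.53, adjusted p = 0.195) and Pdgfra (−0.58, adjusted p = 0.0533) lost their calls with the cell cycle score as a covariate, and Cygb kept its call at −0.87. Pericyte genes rose in 3 of 10 members and fell in 3 (3 and 4 adjusted over the list alone; camera adjusted p = 0.907), with a median of −0.74, a mean of −0.35 and a test direction of up. Mcam, the proteoglycan gene Cspg4 (1.70 ± 0.33, adjusted p = 0.00448) and Cd248, endosialin (0.61 ± 0.09, adjusted p = 0.00106, chosen after its values were seen), rose. The peptidase gene Anpep (−2.01 ± 0.23, adjusted p = 0.000461) and Kcnj8 (−1.88 ± 0.45, adjusted p = 0.0119) and Abcc9 (−1.66 ± 0.43, adjusted p = 0.0166), the subunits of the vascular ATP-sensitive potassium channel, fell. Abcc9 did not pass in limma-voom (−1.44, adjusted p = 0.0857), Kcnj8 (−0.47, adjusted p = 0.559) and Abcc9 (−0.19, adjusted p = 0.824) lost their calls and Cspg4 shrank to 1.06 with the cell cycle score as a covariate, and without WT 2 there were 6 lower members. Macrophage genes fell in 2 of 10 members, Mpeg1 (−2.25 ± 0.48, adjusted p = 0.0067) and Ctss (−2.22 ± 0.59, adjusted p = 0.0179), and rose in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0602). The macrophage list passed without WT 4 (camera adjusted p = 0.0248), WT 5 (0.00735), WWv 1 (0.0162), WWv 2 (0.0156), WWv 3 (0.00501), WWv 4 (0.0184) or WWv 5 (0.0128), with the cell cycle score as a covariate (0.0384), and after correction for gene length and GC content (0.0256). Lower macrophage members numbered 5 without WT 2 and 4 without WT 5, WWv 1, WWv 3, WWv 4 or WWv 5, and Ctss lost its call with the cell cycle score as a covariate (−2.28, adjusted p = 0.0692). Cygb, Pdgfra and Abcc9 overlap genes on the opposite strand, so their reads are uncertain.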

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

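Chosen only after the result was seen were the tests for endothelial cells in WT 2, for its faster growth and for fewer fibroblasts in WWv (which replaced earlier forms), the test of a wrong label on the contractile genes, the test of growth state on the contractile genes alone, and the fit with the cell cycle score.

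A library is listed where its gap to the nearest library of its group, as a share of the whole range of the 5, passed Dixon's 95% limit. Chance alone passes this limit in about 1 of 20 groups. Of 282 groups of 5, over 128 genes and 13 library measures, 28 passed it, against 14.1 by chance, and 14 of the 28 were WT 2. WT 2 was the highest of WT for the mean level of the cell cycle list (gap 0.768 of the range) and for the levels of Smpd3 (0.769), Creb5 (0.717), Ptprb (0.744), Pecam1 (0.751) and Cdh5 (0.736). It was the lowest of WT for Steap4 (0.748), Itgb8 (0.812), C3 (0.790), Bcl3 (0.817), Lum (0.738), Neat1 (0.829), Mt1 (0.747) and Alpl (0.900). WT 5 was the highest of WT for the contractile genes Acta2 (0.755) and Cnn1 (0.789) and the lowest for Pdgfra (0.740) and Pxn (0.743). WWv 1 was the lowest of WWv on the second principal component (0.733) and for Pmaip1 (0.723), and the highest for the share of counts on noncoding RNA genes (0.787), Pdgfra (0.757) and Dnaja1 (0.953). WWv 5 was the lowest of WWv on the first principal component (0.905) and the highest for Cenpa (0.734). WWv 3 was the lowest of WWv for Fdft1 (0.711), Pxn (0.939) and Upk1b (0.778).

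WT 2 lay within the WWv range on the first principal component, with low complement, Lum and Neat1 and high cell cycle and endothelial genes. For a wrong label, 66.9% of the 7127 genes past the threshold without WT 2 were nearer to WWv in WT 2, between the bounds set for this test. Every other library was scored on the genes called without it, 3013 to 4110 genes, with WT 2 kept in the WT mean. On those other gene sets the share nearer to WWv was 71.6% or more in each WWv library and 4.80 to 11.3% in the other WT libraries. The shares therefore do not cover the same genes as the 66.9%. Of the contractile genes called without WT 2, 0 of 19 were nearer to WWv in WT 2. Since at most 2 of 16 in a WWv library lay nearer to WT, this later test argues against a wrong label. Contractile levels vary within WT, however (nearer to WWv in 12 of 18 in WT 5 and in 0 in WT 1, WT 3 and WT 4). If admixed endothelial cells expressed neither list, their RNA would lower contractile and complement genes alike. In WT 2 complement genes stood 0.92 below contractile genes in their shift (−0.92 ± 0.40 SE over member genes, −1.08 and −0.17), and the endothelial list stood 1.37 ± 0.25 higher. That SE treats the member genes of 1 library as independent, and the level of either list in endothelial cells was not tested. Endothelial RNA in WT 2 can therefore not be excluded. For faster growth, the slope of 7090 of the called genes (cell cycle list left out) on the cell cycle score within the groups of the other 9 libraries predicted 0.287 of the shift of WT 2 towards WWv, with a 95% interval of −0.706 to 1.28 that holds both none and all of it, so growth cannot be told apart from other differences of this culture. Culture batch and litter, not given in the sources used here, stay open.

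For the higher contractile and lower complement genes in WWv, removing the trend of each library with gene length and GC content kept at least 0.888 of both medians and both calls, which argues against such bias. The changes of the medians include the shift that this correction gave all genes in common. With the mean level of the fibroblast list as a covariate, the difference in the contractile mean was 1.13 times as large but without WT 2 had a 95% interval of −0.490 to 0.976, and the complement difference went from −0.76 to 0.05 (−0.0713 of its size, interval −0.177 to 0.285) and without WT 2 from −0.98 to −0.16 (interval −0.614 to 0.291), so fewer fibroblasts in the WWv cultures cannot be told apart from genotype for either gene group, since without WT 2 each interval holds 0 and also a difference above 0.5 of its size, although the complement values go with it. With the cell cycle score as a covariate the contractile median went from 0.44 to 0.60, 1.35 times as large (camera adjusted p = 4.12e-17). Without WT 2 it went from 0.41 to 1.04, where 3 of all genes were called but the mean of the list still differed (1.03 ± 0.27 SE, 95% interval 0.368 to 1.69). That fit extends a slope whose interval holds 0 (−2.57 to 0.159) between groups whose scores do not overlap (WT 5.06 to 5.22, WWv 5.48 to 5.69). Neither fit made the contractile difference smaller, which gives no sign of growth state as its cause. The groups overlap in the score only through WT 2, so growth state is not excluded for the contractile genes. The complement median went from −0.98 to −0.20, 0.206 of its size, and its call ended because the change itself shrank (camera adjusted p = 0.0574), while without WT 2 it went from −1.24 to −0.92, so for complement genes growth state and genotype cannot be told apart, since the score differed between the groups and this comparison leaned on WT 2. Loss of Kit signalling, the difference that the design names, was not tested apart from the culture, litter and background of the mice, and stays open for both gene groups.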

How the results depend on the processing

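The fit without WT 2 and WWv 1 and the fit with the cell cycle score as a covariate were chosen after seeing the data; for each change below the cause was not tested unless it is stated. The 4274 calls (1940 higher, 2334 lower) became 983 higher and 3599 lower with library size only, 1827 (839 and 988) at an adjusted p under 0.01, which is stricter by construction, and 35 (6 and 29) against a log2 fold change of at least 1, where Kit, at −1.04, did not pass. Limma-voom with quality weights gave 7401 (3595 and 3806), the fit without WT 2 and WWv 1 gave 7111 (3361 and 3750), and the cell cycle score as a covariate gave 1671 (939 and 732), 1317 of them among the 4274. RLE (4243), upper quartile (4243), no low-count filter (3571), 1 CPM in 5 libraries (3854), robust dispersions (4251), no mitochondrial genes (4277), limma-voom (4165), DESeq2 (5020) and an adjusted p under 0.1 (5759) gave counts within 1.5 times of 4274. With each library left out in turn, calls ranged from 3013 to 7127, higher calls from 1286 to 3507, lower calls from 1721 to 3620, the Kit log2 fold change from −1.24 to −0.86 with its call kept, and lists past the threshold from 10 to 12; 1 library fewer lowers the power by construction, while the rise to 7127 came without WT 2. Lists past the threshold numbered 10, and 0 with an estimated correlation, which allows for genes that move together, 11 by fry, 9 with library size only, 12 with 1 CPM in 5 libraries, 10 without WT 2 and WWv 1 and 13 with the covariate. With the covariate the log2 fold changes of C3 (0.30), Pecam1 (−0.50), Cdh5 (−0.27) and Mki67 (−0.11) and the lists of MAPK output (median −0.056), cell cycle genes (median 0.023, downward by camera) and endothelial genes (−0.48) changed direction; the cell cycle list is the covariate itself, so its change follows from the construction. Pecam1 ranged from −0.011 (without WWv 4) to 0.98 (without WT 2), the median of the endothelial list from −0.0088 (without WT 4) to 0.30 (without WT 2), and that of the collagens from −0.20 (without WT 2) to 0.021 (without WT 5), with −0.15 when WT 2 and WWv 1 were both left out. Over all other settings, 2402 values of the 173 named genes comprised 2123 with the same direction and call, 266 without the call, 9 with a new call and 4 reversed, and over the fits without 1 library, 1730 comprised 1566, 159, 4 and 1. Of the 266 lost calls, 153 came with the minimum log2 fold change of 1, which is stricter by construction. A further 70, and the 4 reversals, came with the cell cycle score as a covariate. For the lists past the threshold in any setting, 174 values over other settings comprised 130 with the same direction and call, 20 without the call, 20 with a new call and 4 reversed, and 250 over the fits without 1 library comprised 226, 3, 19 and 2. The replicate numbers showed no clear pairing of the libraries of the 2 groups. Those with the same number correlated at −0.092 to 0.308 (mean 0.0336) in their deviations from the group means. Of 5 WT libraries 1 correlated best with its own number. So few correlations cannot exclude a batch or litter shared by libraries of the same number. With the replicate number as a block there were 3636 calls (1693 higher, 1943 lower), 3412 of them among the 4274, and 15 lists, and C3 (−1.35, adjusted p = 0.0929) was among 14 named genes no longer called. At these totals 98.5% of simulated 4-fold changes were recovered, but changes of 1.5-fold were missed in part (71.6% recovered). All were placed in genes above a mean of 1 CPM in WT. Large changes in such genes were thus mostly recovered at these totals in the simulation. It drew each gene independently, without shifts of a whole library such as that of WT 2, and did not vary depth. What limits the calls in the real libraries, and recovery in genes with fewer counts, was not tested.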

Other observations

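The fit with the cell cycle score was the only test of this part chosen after its result was seen; the lists, the window around Kit and the other splits of the libraries were fixed before. Matrix genes changed in both directions. Of the 23 fibrillar and basement membrane collagens 4 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.845; median −0.08, mean −0.01, test direction up; camera adjusted p = 0.00437 with the cell cycle score as a covariate), and chains of the same collagen parted, with Col6a3 higher (1.46 ± 0.21, adjusted p = 0.00127) and Col6a1 lower (−0.63 ± 0.17, adjusted p = 0.0181). Lower collagens numbered 9 without WT 2, 1 without WT 1, and 2 without WT 3, WT 4, WT 5, WWv 1, WWv 2, WWv 3 or WWv 4. Elastic fibre and matrix glycoprotein genes fell in 9 of 44 members and rose in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.347), with Fbn2, a fibrillin of developing elastic fibres, at −1.87 ± 0.38 (adjusted p = 0.00569) and Mfap2, a microfibril protein, at −1.55 ± 0.15 (adjusted p = 0.000247). Without WT 2 they numbered 16 lower and 6 higher, and higher members numbered 0 or 1 without WT 1, WT 3, WT 4, WWv 2, WWv 3, WWv 4 or WWv 5. Matrix proteases and inhibitors rose in 8 of 31 members and fell in 10 (10 and 12 adjusted over the list alone; camera adjusted p = 0.785), with the stromelysin gene Mmp3 at −2.69 ± 0.36 (adjusted p = 0.0008), and without WWv 4 the higher ones numbered 5. Markers of the synthetic, dedifferentiated state rose in 5 of 22 members and fell in 5, among them Mmp3 and Lum (5 and 6 adjusted over the list alone; camera adjusted p = 0.714; median 0.18, mean −0.33, test direction up). The higher ones numbered 2 without WT 1, WT 3, WT 4, WT 5, WWv 2, WWv 3 or WWv 4 and 3 without WWv 5, and the lower ones 3 without WWv 2. Osteochondrogenic genes rose in 4 of 24 members, among them Msx2 (1.05 ± 0.22, adjusted p = 0.00619), and fell in 3, among them the phosphatase gene Alpl (−2.14 ± 0.47, adjusted p = 0.0078; 4 and 3 adjusted over the list alone; camera adjusted p = 0.925; median −0.16, mean −0.17, test direction up), with 7 lower without WT 2 and 1 without WWv 3. Lost with the cell cycle score as a covariate were the calls of Col6a1 (−0.24, adjusted p = 0.438), so that the collagen chains no longer parted past the threshold, Lum (−1.52, adjusted p = 0.0709), Alpl (−0.71, adjusted p = 0.411) and Msx2 (0.70, adjusted p = 0.0935).

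Genes of vessel tone changed in opposite directions within 1 pathway. The subunits of soluble guanylate cyclase, the nitric oxide receptor, parted, with Gucy1b1 higher (1.27 ± 0.10, adjusted p = 9.88e-05) and Gucy1a1 lower (−1.20 ± 0.24, adjusted p = 0.00518). The phosphodiesterase gene Pde1a (−1.43 ± 0.24, adjusted p = 0.00241) and the prostacyclin receptor gene Ptgir (−1.16 ± 0.16, adjusted p = 0.000978) were lower. The vasoactive list held 5 higher and 5 lower of 32 (5 and 5 adjusted over the list alone; camera adjusted p = 0.925), with 12 lower without WT 2. Calcium handling and channel genes rose in 9 of 26 members and fell in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.182; median 0.20, mean −0.09, test direction up), and Kcnma1, the pore of the large-conductance potassium channel, was lower (−3.18 ± 0.52, adjusted p = 0.00205); 5 rose without WT 3, WWv 2 or WWv 3. Growth factors and their receptors rose in 11 of 47 members and fell in 13 (13 and 15 adjusted over the list alone; camera adjusted p = 0.789; median 0.07, mean −0.02, test direction up, median −0.01 with library size only), with Igfbp5 higher (1.65 ± 0.18, adjusted p = 0.000388) and Vegfd lower (−1.46 ± 0.27, adjusted p = 0.0039). Wnt genes rose in 2 of 32 members and fell in 7 (2 and 7 adjusted over the list alone; camera adjusted p = 0.366), with the antagonist gene Sfrp1 at −1.59 ± 0.39 (adjusted p = 0.0126), and 4 and 16 without WT 2. Notch genes rose in 2 of 17 members and fell in 2 (2 and 3 adjusted over the list alone; camera adjusted p = 0.925; median −0.02, mean −0.22, test direction up), the ligand gene Dll1 among the lower (−2.75 ± 0.73, adjusted p = 0.0176). Without WT 2 the higher Notch genes numbered 5, without WT 4 1, and without WT 1, WT 3, WT 5 or any of WWv 2 to WWv 5 0; the lower numbered 1 without WT 3, WT 4, WT 5 or WWv 3. Of the Hox genes, which record position along the body axis, 1 of 27 rose, Hoxb2 (0.33 ± 0.06, adjusted p = 0.00382), and 1 fell, Hoxa11 (−2.60 ± 0.73, adjusted p = 0.0226; 1 and 0 adjusted over the list alone; camera adjusted p = 0.734; median 0.18, mean −0.14, test direction up). Hoxa11 lost its call without WT 3 (−2.28), WT 5 (−2.35), WWv 2 (−2.49) or WWv 4 (−2.37), and 7 Hox genes rose and 2 fell without WT 2 and 3 and 2 without WWv 1. In limma-voom Hoxa11 (−2.63, adjusted p = 0.0529) and Dll1 (−2.49, adjusted p = 0.115) were not called. The calls of Gucy1a1 (−0.78, adjusted p = 0.0991), Sfrp1 (−0.31, adjusted p = 0.53), Dll1 (−0.26, adjusted p = 0.892) and Hoxa11 (−0.66, adjusted p = 0.682) were lost with the cell cycle score as a covariate, and the changes of Pde1a (−0.70), Vegfd (−0.53) and Kcnma1 (−1.57) shrank by more than 1.5 times with their calls kept.

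The lists of NRF2 targets, heat shock, the unfolded protein response, oxidative phosphorylation, mitochondrially encoded genes and lipid uptake did not pass camera with all libraries, whereas with the cell cycle score as a covariate the NRF2 (camera adjusted p = 7.51e-05), unfolded protein response (0.00609) and mitochondrially encoded (0.0161) lists did. NRF2 target genes fell in 6 of 33 members and rose in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.182), with the metallothionein gene Mt1 at −1.11 ± 0.16 (adjusted p = 0.00132), G6pdx, which feeds the pentose phosphate pathway, at −0.82 ± 0.10 (adjusted p = 0.000676) and Gstm1 at −0.56 ± 0.11 (adjusted p = 0.00602), and without WT 2 there were 6 higher. Heat shock genes rose in 2 of 15 members, Hspb1 (0.73 ± 0.06, adjusted p = 0.000105) and Dnajb1 (0.26 ± 0.05, adjusted p = 0.00519), and fell in 1, Dnaja1 (−0.24 ± 0.07, adjusted p = 0.0212; 2 and 1 adjusted over the list alone; camera adjusted p = 0.128). The median of that list, 0.07, turned to −0.02 with library size only, 7 rose without WT 2, and Dnaja1 lost its call without WWv 2 (−0.23), WWv 3 (−0.23), WWv 4 (−0.24) or WWv 5 (−0.23). Unfolded protein response genes rose in 4 of 33 members, among them the sensor gene Atf6 (0.48 ± 0.06, adjusted p = 0.000676), and fell in 1 (2 and 0 adjusted over the list alone; camera adjusted p = 0.46; mean 0.04, median −0.00071, which turned to 9.2e-05 with RLE size factors). Higher ones numbered 2 without WT 3, WT 4 or any of WWv 2 to WWv 5, and lower ones 5 without WT 2 and 0 without any other library except WT 4 and WWv 5. Oxidative phosphorylation genes passed in 0 of 28 (0 adjusted over the list alone; camera adjusted p = 0.532; median 0.04, −0.05 with library size only), with 10 higher and 1 lower without WT 2 and 1 lower without WWv 1. Mitochondrially encoded genes passed in 0 of 10 (0 adjusted over the list alone; camera adjusted p = 0.347), with 2 higher in DESeq2 and without WT 1. Lipid uptake and lipogenesis genes rose in 3 of 29 members and fell in 4 (3 and 4 adjusted over the list alone; camera adjusted p = 0.314), with Apoe, the lipoprotein ligand, at −1.47 ± 0.16 (adjusted p = 0.000388) and the fatty acid chaperone gene Fabp4 at −1.13 ± 0.15 (adjusted p = 0.000676); 6 rose and 10 fell without WT 2, and 1 rose without WT 1 or WWv 2. Dnajb1 lost its call with the cell cycle score as a covariate (0.21, adjusted p = 0.0626), and the change of Mt1 shrank to −0.65.

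Adipocyte genes rose in 1 of 7 members and fell in 3, among them the lipase gene Lipe (−0.70 ± 0.14, adjusted p = 0.00466; 1 and 3 adjusted over the list alone; camera adjusted p = 0.314), and 0 rose without WT 1, WT 3, WT 4, WT 5, WWv 2, WWv 3 or WWv 4. Mesothelial and epithelial genes rose in 1 of 9, Upk1b (1.76 ± 0.40, adjusted p = 0.0091; 1 and 0 adjusted over the list alone; camera adjusted p = 0.182), and in 2 without WT 2. Schwann and neural genes rose in 1 of 12 and fell in 1, Cnp (−0.35 ± 0.08, adjusted p = 0.00832; 1 and 1 adjusted over the list alone; camera adjusted p = 0.925; median 0.27, mean 0.13, test direction down). Striated muscle genes rose in 2 of 8, Tnnt2 (1.44 ± 0.19, adjusted p = 0.000712) and Acta1 (1.38 ± 0.22, adjusted p = 0.00185), and fell in 2, Tnni3 (−1.72 ± 0.30, adjusted p = 0.00274) and Tnnt3 (−1.12 ± 0.26, adjusted p = 0.00966; 2 and 2 adjusted over the list alone; camera adjusted p = 0.925; median −0.11, mean −0.03, test direction up). Melanocyte genes rose in 0 of 6 and fell in 2, Kit and the transcription factor gene Mitf (−0.47 ± 0.12, adjusted p = 0.0155; 0 and 2 adjusted over the list alone; camera adjusted p = 0.182). Of the lists too short to test, the lymphocyte list held Trac higher (1.39 ± 0.21, adjusted p = 0.00153) and Lck lower (−1.33 ± 0.34, adjusted p = 0.0149) among 2 tested genes, the mast cell list held Kit as its 1 lower of 3 tested genes, with 2 higher without WT 2, and the erythroid list held 0 tested genes. Of 4 tested sex chromosome transcripts Ddx3y rose (0.23 ± 0.06, adjusted p = 0.0157, 0.15 with library size only) and 2 fell, among them Kdm5d (−0.35 ± 0.07, adjusted p = 0.00576), and 1 fell without WT 3, WT 5 or WWv 2. The cell cycle score as a covariate ended the calls of Tnnt3 (−0.69, adjusted p = 0.202), Upk1b (1.58, adjusted p = 0.117), Mitf (−0.17, adjusted p = 0.384), Cnp (−0.30, adjusted p = 0.0854) and Kdm5d (−0.31, adjusted p = 0.0577), and the replicate number as a block that of Lck (−1.30, adjusted p = 0.0517). Among the genes of this part, Fbn2, Kcnma1, Dll1, Hoxb2, Hoxa11, G6pdx, Dnaja1, Lipe and Cnp overlap genes on the opposite strand and Gucy1a1, Lck and Tnni3 genes on their own, so their reads are uncertain.

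Alleles linked to Kit could account for calls near the gene if a segment of another background travels with the mutations. The background of the mice was not given in the sources used here. Of 60 tested genes within 10 Mb of Kit on chromosome 5, 19 were past the threshold (31.7%), Pdgfra, named after its values were seen, among them, against 4254 of 15120 elsewhere (28.1%; odds ratio 1.18, 95% interval 0.648 to 2.09, two-sided Fisher exact p = 0.566). The interval holds both no excess and the 1.5-fold excess named in advance, so linked alleles and genotype cannot be told apart for these genes.

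The groups of the labels gave 4274 genes past the threshold. Of 126 possible splits of the 10 libraries into 5 and 5, 100 were drawn, the real one included. The highest of the other splits drawn gave 2180, so 1 of 100, the real one, reached 4274. None of the other splits drawn gave as many genes, but the test cannot tell genotype from culture, litter or background. The split with 2180 genes exchanged WT 2 and WWv 1. The exchanges of WT 2 with WWv 2 and with WWv 5 were not among the splits drawn.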
